A study of Mus musculus with 24 samples.

How the data were processed

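The samples were 24 libraries of liver and ileum RNA from Ldlr-/- mice on regular chow (CHD) or a high-fat diet (HFD), given control water or a peptide, in 8 groups of 3. Per the labels' protocols, RNA was extracted with TRIzol, depleted of ribosomal RNA and made into stranded dUTP libraries. The submitters' processing notes name, without roles or order, the mouse build mm9, Bowtie2 2.1.0, TopHat2 2.1.0, HOMER 4.8.3 and DESeq2. The notes do not say whether reads were counted by strand, so it is unknown whether reads of overlapping and antisense genes were told apart.

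The deposited files were 4 tables of the authors' own comparisons, 1 for each tissue and diet, each with 34600 RefSeq transcripts. Per the file headers the first value was the mean over the libraries of a table of the normalized counts, a signal pooled over both groups. The authors' fold change and its standard error were in log2 units, per the file headers, and their values showed that both had been shrunken towards 0. A test score, equal to the fold change over its standard error, was deposited beside them. Each p-value and adjusted p-value was the authors' own, per the file headers. Adjusted p-values of low-count transcripts were left blank in the deposited tables, so that in liver on CHD 24269 transcripts had a p-value and 4032 an adjusted one. No table held values of single libraries, so total counts per library, the spread within a group and the precision that depth gives are unknown. The direction of the contrasts was not stated and was read as peptide over control. Fold changes of the tables of a tissue went together across genes, which are not independent replicates (Pearson's r of the statistics 0.198 in liver and 0.234 in ileum), but this does not settle the direction.

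Tests, gene lists and the rule for named genes were chosen before the data were examined, for tables of counts. Since the deposited files held another unit, the authors' adjusted p-values took the place of a refit, and tests that need single libraries were not run. These include the comparison of the diets in control mice. Transcripts were named from a RefSeq table of assembly GRCm38.p6, used for names alone because the authors' build differed, and 34268 were matched and 332 were not. Each of 24522 genes was represented in a tissue by its transcript with the highest mean. Transcripts of a gene share reads, as do similar gene copies, such as those within the defensin, histone and globin families, whose values are uncertain where reads could be split. Genes passed at an adjusted p under 0.05.

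The dependence on diet was tested per gene as the difference of the fold changes (HFD minus CHD) over the root of the summed squares of the standard errors, with normal p-values and Benjamini-Hochberg adjustment, on genes with a mean of at least 10 in both tables. Gene lists, 21 of pathways and 23 of markers, were tested with limma 3.58.1 (cameraPR) in R 4.3.3 on the scores of genes with a mean of at least 10, for lists with at least 3 measured genes, with an inter-gene correlation preset at 0.01. They were tested again at 0.05 and 0.2, since a correlation cannot be estimated without single libraries. Adjustment was over the lists of a comparison, and counts adjusted over the list alone were given beside it. Overlaps between diets were tested with one-sided Fisher's exact tests on genes tested in both tables. GC content and length came from GENCODE M21 transcripts, and the correction took the residual of the score on a linear and quadratic trend of both. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

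Named were the 10 higher and 10 lower genes with the largest fold changes among those that passed and lay in the upper part of the tested genes by mean (5 and 5 for the diet dependence), up to 4 members of each list, and a fixed set of lipid, bile acid and defence genes. The rule also asked that the groups not overlap, which could not be checked. Genes shared between diets, further list members and the set of histone genes were chosen after their values were seen.

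The procedures for genes were tested on simulated data with 100 genes changed by each size and the others unchanged, and for the 4 tables with an added trend with transcript length. The authors' own test could not be simulated. Changes of 1 log2 unit were recovered for 100%, 95%, 88% and 100% of genes in liver on CHD, liver on HFD, ileum on CHD and ileum on HFD, and changes of 0.5 for 34%, 31%, 25% and 39%. With the correction, the shares at 1 were 99%, 96%, 92% and 99%. Unchanged genes that passed numbered 33, 24, 37 and 42 without the correction and 11, 5, 7 and 9 with it. The same trend was added to each table. In the data Spearman's rho between the score and length was -0.042 in liver on CHD and -0.017 in liver on HFD. In liver on CHD 9844 genes were simulated, while 2588 had a deposited adjusted p. The simulated changes were set over the shrunken SE without being shrunken themselves. These counts and shares therefore do not carry over to the reported calls. Differences of 1 between diets were recovered for 77% of genes in liver and 46% in ileum, and differences of 0.5 for 9% and 2%, with 5 and 1 unchanged genes passing. For lists with at least 5 measured genes, the real scores were shuffled over genes before lists were shifted. Lists shifted by 1 unit of the score were recovered in 87.5%, 50.0%, 50.0% and 52.5% of cases. Shuffling removes correlation between genes, so these shares do not carry over to lists of correlated genes. The alternatives tried were another threshold, other filters on the mean, scores divided by their spread, the GC and length correction, fold changes with the shrinkage undone, transcripts in place of genes, and for lists other correlations, ranks and a narrower set of genes.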

Results

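The libraries came from liver and ileum of mice without a functional low-density lipoprotein receptor (Ldlr-/-), a strain used to study high blood cholesterol and atherosclerosis. The mice ate regular chow (CHD) or a high-fat diet (HFD). For 2 weeks their drinking water held 1% sucrose in all groups, with either a peptide at 180 µM (200 µg/mL) or a control solution of PBS. The 24 libraries of ribosomal RNA-depleted total RNA formed 8 groups of 3, and the question was how the peptide altered transcription in each tissue on each diet. The values were those of 4 tables of the authors' own peptide comparisons, each with 34600 RefSeq transcripts, so the total count of each library and the spread within a group were unknown. The error beside a gene's fold change is the standard error (SE) in the authors' deposited table, and those fold changes were shrunken towards 0. The error beside a difference between diets was computed from the SE of both tables. The tables did not name the direction of the contrast. It was read here as peptide over control, and every direction in a table would invert if the authors had set it the other way. The labels did not tie libraries to animals or cages, so the p-values measure only the spread between these libraries.

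Ldlr itself was still counted, at mean normalized counts of 1061 in liver on CHD, 1592 in liver on HFD, 1103 in ileum on CHD and 566 in ileum on HFD in the authors' deposited tables. Reads outside a disrupted part of a gene are counted as usual, so these means do not check the genotype. The peptide comparison of Ldlr passed in no table, with adjusted p-values of 0.995, 0.970, 0.318 and 0.908 in the authors' deposited tables.

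In the liver on CHD, genes of fatty acid oxidation were lower with the peptide and genes of cholesterol synthesis were higher. In the authors' deposited table Cyp4a14 and Cyp4a10, which encode fatty acid omega-hydroxylases under the control of PPAR-alpha, fell by 1.06 ± 0.15 (SE) and 1.02 ± 0.15 on the log2 scale (adjusted p = 6.23e-09 for each). Ehhadh, an enzyme of peroxisomal beta-oxidation, fell by 0.96 ± 0.13 (adjusted p = 5.07e-09 in the authors' deposited table). Per the authors' deposited table Retsat, a retinol saturase, also fell by 0.97 ± 0.16, Acot1, an acyl-CoA thioesterase, by 0.87 ± 0.17, Angptl4, an inhibitor of lipoprotein lipase, by 0.87 ± 0.17, and the peroxisomal thiolase Acaa1b by 0.76 ± 0.12. Of the 22 measured genes of the fatty acid oxidation and PPAR-alpha list, 21 had negative fold changes, 7 fell in the test over all genes and 14 when adjusted over the list alone. The list as a whole was lower (limma's list test, adjusted p = 4.59e-42, and 5.13e-10 with an assumed inter-gene correlation of 0.2). All 23 measured cholesterol synthesis genes had positive fold changes, and the list was higher (adjusted p = 3.49e-12, and 0.00612 with a correlation of 0.2). Of these genes Sc5d, a late enzyme of the pathway, rose by 0.52 ± 0.14 in the authors' deposited table (adjusted p = 0.0177), and 6 passed when adjusted over the list alone. Hmgcr, the rate-limiting enzyme, stood at 0.35 ± 0.17 and did not pass (adjusted p = 0.488 in the authors' deposited table).

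Further genes changed in the liver on CHD. Higher in the authors' deposited table were Serpina3k (0.75 ± 0.13), a serine protease inhibitor made by hepatocytes, Pdcd4 (0.71 ± 0.13), the organic anion transporter Slco1a1 (0.70 ± 0.15) and the glycolytic enzyme Pklr (0.55 ± 0.14). Lower, also in the authors' deposited table, were Csad (-0.76 ± 0.15), an enzyme of taurine synthesis, the glucokinase gene Gck (-0.67 ± 0.17), Lpin2 (-0.64 ± 0.12), Aldh3a2 (-0.58 ± 0.12) and the nuclear noncoding RNA Neat1 (-0.68 ± 0.19). Fatty acid synthesis genes, 14 of 20 with positive fold changes and Pklr the 1 that passed over all genes, were higher as a list (adjusted p = 0.00288, but adjusted p = 0.318 with a correlation of 0.2). When adjusted over the list alone 2 passed. All 14 antigen presentation genes had negative fold changes and the list was lower (adjusted p = 5.70e-05, but 0.0946 with a correlation of 0.2). Over all genes or adjusted over the list alone 0 of them passed. Limited to genes with a deposited adjusted p, the list did not pass (adjusted p = 0.139). Among cell type markers, 12 of 14 macrophage and Kupffer cell genes had negative fold changes (median -0.11, adjusted p = 0.0263, but 0.394 with a correlation of 0.2). Limited to genes with a deposited adjusted p, that list did not pass either (adjusted p = 0.192). Hepatocyte markers had a median of 0.08 (adjusted p = 0.0128, but 0.318 with a correlation of 0.2). Genes of the unfolded protein response were higher (14 of 17 positive, 0 passed over all genes, 1 adjusted over the list alone; adjusted p = 4.76e-04, but 0.182 with a correlation of 0.2). Red blood cell markers were higher too (4 of 5 positive, adjusted p = 0.0111, but 0.138 with a correlation of 0.2). This list holds similar globin copies, which share reads, so its p-values may be too small. Heat shock genes were lower (7 of 10 negative, adjusted p = 0.0263, but 0.318 with a correlation of 0.2). Of 24 lists tested 9 passed, and 2 of them also with a correlation of 0.2. The bile acid enzymes Cyp7a1 (0.31 ± 0.17, adjusted p = 0.626) and Cyp8b1 (-0.07 ± 0.15, adjusted p = 0.995) did not pass in the authors' deposited table. Nor did Fasn (0.46 ± 0.16, adjusted p = 0.147), Scd1 (-0.08 ± 0.16, adjusted p = 0.995) or Abca1 (0.02 ± 0.13, adjusted p = 0.995) in the authors' deposited table. In all, 28 of 2588 genes with an adjusted p passed in the authors' deposited table, 8 higher and 20 lower. The authors' filter had left no transcript with a mean under 136.5 normalized counts. Of the 9835 genes with a mean of at least 10, 461 had an unadjusted p under 0.05 in the authors' deposited table, where 492 were expected by chance. When the statistics, which were narrower than a standard normal distribution (spread 0.890), were divided by their spread, 71 genes passed, 38 higher and 33 lower.

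In the liver on HFD, acute phase genes, metallothioneins among them, were higher with the peptide, while genes of fatty acid oxidation and of fatty acid synthesis were lower. Mt2 and Mt1, which encode metal-binding proteins induced by zinc, glucocorticoids and inflammation, rose by 2.48 ± 0.16 and 1.68 ± 0.13 in the authors' deposited table, or 5.60-fold and 3.21-fold (adjusted p = 5.14e-52 and 8.20e-32). Socs3, a feedback inhibitor of cytokine signalling, rose by 1.13 ± 0.19, the transcription factor Junb by 0.90 ± 0.15, the adhesion molecule Icam1 by 0.71 ± 0.17 and the chemokine Cxcl10 by 0.74 ± 0.21 in the authors' deposited table. Of 24 acute phase genes 22 had positive fold changes, 4 rose in the test over all genes and 12 when adjusted over the list alone, and the list was higher (adjusted p = 2.02e-28, and 1.52e-06 with a correlation of 0.2). The 4 that rose were Mt2, Mt1, Socs3 and Apcs, so the list holds both metallothioneins. The interferon response list (30 of 30 genes positive, 1 risen over all genes, 7 adjusted over the list alone) was higher, with adjusted p = 4.42e-12, and 0.00769 with a correlation of 0.2. The list of inflammatory cytokines, chemokines and receptors (17 of 17 positive, 1 risen, 3 adjusted over the list alone) was higher too, with adjusted p = 1.11e-06, and 0.0244 with a correlation of 0.2. Antigen presentation genes (17 of 17 positive, 0 passed, 4 adjusted over the list alone) and immediate early genes (13 of 14 positive, 1 risen, 2 adjusted over the list alone) were higher as lists as well (adjusted p = 3.73e-09 and 2.52e-07, and 0.00634 and 0.00897 with a correlation of 0.2).

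The fatty acid oxidation and fatty acid synthesis lists were lower in the liver on HFD. The cholesterol synthesis and bile acid lists were lower too, but not with a correlation of 0.2 (adjusted p = 0.244 and 0.0775). The list of apolipoproteins and lipoprotein assembly (10 of 17 positive, adjusted p = 0.767) and the sterol efflux list (4 of 11 positive, adjusted p = 0.807) did not pass. Ehhadh fell by 1.33 ± 0.15, Cyp4a14 by 1.31 ± 0.14, Acot1 by 1.28 ± 0.15, Acot2 by 1.12 ± 0.19, Acaa1b by 1.00 ± 0.15 and Acox1, the first enzyme of peroxisomal beta-oxidation, by 0.57 ± 0.14 in the authors' deposited table. Of 22 genes of the fatty acid oxidation list, 21 had negative fold changes, 9 fell in the test over all genes and 15 when adjusted over the list alone, where 1 also passed as higher. The list was lower (adjusted p = 1.49e-32, and 1.10e-07 with a correlation of 0.2). Fatty acid synthesis genes were lower (18 of 20 negative, 4 fallen, 11 adjusted over the list alone; adjusted p = 4.42e-12, and 0.00224 with a correlation of 0.2). Those that fell in the authors' deposited table were Me1 (-0.82 ± 0.17), Srebf1 (-0.57 ± 0.11), which encodes the main transcription factor of lipogenesis, Fads2 (-0.49 ± 0.12) and Gpam (-0.48 ± 0.13). Cholesterol synthesis genes were lower as a list (16 of 22 negative, adjusted p = 0.00350, but 0.244 with a correlation of 0.2). Hmgcr fell by 0.66 ± 0.12 in the authors' deposited table (adjusted p = 2.47e-05), and with Insig1 it made up the 2 genes that passed when adjusted over the list alone. Genes of bile acid synthesis and transport were lower (13 of 16 negative, 3 fallen over all genes and the same number adjusted over the list alone; adjusted p = 9.83e-05, but 0.0775 with a correlation of 0.2). These were Nr0b2 (-0.82 ± 0.19), a repressor induced by bile acids, Cyp7a1 (-0.65 ± 0.15), the rate-limiting enzyme of bile acid synthesis, and the bile acid receptor Nr1h4 (-0.47 ± 0.12) in the authors' deposited table.

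Further single genes changed in the liver on HFD. Tsku, a secreted proteoglycan, fell by 1.64 ± 0.17, the transferrin receptor Tfrc by 1.41 ± 0.16, the glycogen-targeting subunit Ppp1r3b by 1.07 ± 0.14, the lysophospholipid transporter Mfsd2a by 0.84 ± 0.17 and Gck by 0.83 ± 0.16 in the authors' deposited table. Higher in the authors' deposited table were Bmf (1.04 ± 0.18), the tight junction gene Cldn1 (0.96 ± 0.15), the amino acid transporter subunit Slc3a1 (0.91 ± 0.18), Retreg1 (0.74 ± 0.13) and Atf5 (0.71 ± 0.13). Pck1, a gluconeogenic enzyme, rose by 0.58 ± 0.14 in the authors' deposited table. The gluconeogenesis and glycolysis list was lower (11 of 16 negative, 2 risen and 3 fallen; adjusted p = 0.00696, but 0.244 with a correlation of 0.2). Clock genes went both ways: Nr1d1 rose by 0.84 ± 0.16 while Per2 fell by 0.77 ± 0.18 and Cry1 by 0.76 ± 0.20 in the authors' deposited table. Their list did not pass (adjusted p = 0.387). Markers of red blood cells were higher with the peptide (5 of 5 positive, median 0.56, adjusted p = 9.52e-07, and 7.85e-04 with a correlation of 0.2). In the authors' deposited table Hba-a1, whose values equal those of its copy Hba-a2, rose by 0.60 ± 0.16. Hbb-b1 and Hbb-bs had nearly equal values there (means of 414.7 and 414.9, fold changes of 0.56 each). The 5 markers are thus not separate measurements, and the p-values of the list may be too small. Macrophage and Kupffer cell markers had a median of 0.18 (adjusted p = 0.0274, but 0.271 with a correlation of 0.2). Heat shock genes (10 of 11 negative, adjusted p = 0.0141, but 0.244 with a correlation of 0.2) and genes of xenobiotic metabolism (20 of 26 negative, adjusted p = 0.0154, but 0.290 with a correlation of 0.2) were lower as lists. Hepatocyte markers (10 of 13 positive, median 0.14, adjusted p = 0.00728, but 0.244 with a correlation of 0.2) and genes of the unfolded protein response (13 of 19 positive, adjusted p = 0.0176, but 0.271 with a correlation of 0.2) were higher. Of 27 lists tested 16 passed, and 8 of them also with a correlation of 0.2. Fasn (-0.61 ± 0.21, adjusted p = 0.120), Scd1 (-0.40 ± 0.16, adjusted p = 0.239), Cyp8b1 (-0.02 ± 0.15, adjusted p = 0.984) and Abca1 (-0.17 ± 0.10, adjusted p = 0.585) did not pass in the authors' deposited table. In total 129 of 8314 genes passed in the authors' deposited table, 53 higher and 76 lower, and 80 passed, 33 higher and 47 lower, when the statistics were divided by their own spread of 1.09.

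**Figure D1:**
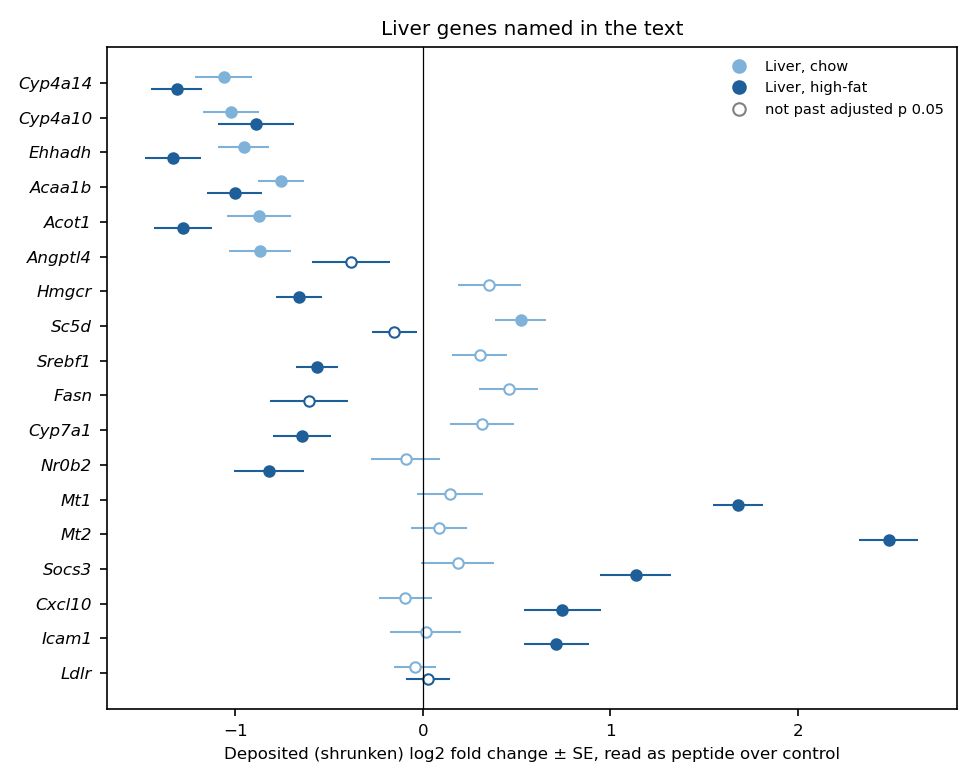
Log2 fold changes of 18 liver genes named in the text, from the authors' deposited tables, read as peptide over control (horizontal axis, log2 units), on CHD (light) and HFD (dark). Bars are the authors' SE and open points did not pass an adjusted p of 0.05: fatty acid oxidation genes from Cyp4a14 to Acot1 lie left of 0 on both diets, and Mt2 lies at 2.48 on HFD and 0.09 on CHD.

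The test of the difference between the diets asked in which genes the peptide effect in the liver differed. Of 9814 genes 15 differed, 7 more positive and 8 more negative on HFD. The difference, HFD minus CHD, was 2.40 ± 0.22 (SE) for Mt2, 1.54 ± 0.22 for Mt1, 1.04 ± 0.24 for Junb, 1.00 ± 0.22 for Csad and 0.81 ± 0.20 for Klf9. It was -1.46 ± 0.25 for Tsku, -1.45 ± 0.24 for Tfrc, -1.08 ± 0.23 for Ppp1r3b, -1.06 ± 0.26 for Fasn, -1.02 ± 0.21 for Hmgcr, -0.96 ± 0.23 for Cyp7a1 and -0.87 ± 0.18 for Srebf1. As lists, acute phase genes (18 of 20 more positive, median difference 0.36, adjusted p = 4.18e-20), antigen presentation genes (14 of 14, 0.53, adjusted p = 1.06e-15) and interferon response genes (22 of 26, 0.38, adjusted p = 3.92e-10) were more positive on HFD. Fatty acid synthesis genes (18 of 20 more negative, median difference -0.46, adjusted p = 6.88e-16) and cholesterol synthesis genes (20 of 22, -0.37, adjusted p = 1.34e-12) were more negative. With a correlation of 0.2 the adjusted p-values of these 5 lists were 4.15e-05, 4.15e-05, 0.0119, 2.37e-04 and 0.00237. Over all genes 2, 0, 0, 2 and 1 of their members passed, and 7, 6, 1, 9 and 9 adjusted over the list alone. The fatty acid oxidation list, lower on both diets, did not differ past the threshold (median difference -0.09, adjusted p = 0.290). With the shrinkage of the fold changes undone, 9 genes differed, all among the 15, and of the genes named here Fasn, Junb and Ppp1r3b no longer passed. Corrected for length and GC content, Cyp7a1 no longer passed (adjusted p = 0.0720). Of 2587 genes tested in both of the authors' deposited tables, 10 fell on both diets where 0.302 were expected for independent lists of the same sizes (one-sided Fisher's exact test, p = 2.91e-14). These were Acaa1b, Acot1, Aldh3a2, Crat, Cyp4a10, Cyp4a14, Ehhadh, Ephx2, Gck and Retsat, and 0 genes rose on both. The exact test takes genes as independent, which genes regulated together are not, so its p-value may be too small.

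In the ileum on CHD, genes of cell division, replication-dependent histone genes and Paneth cell genes were higher with the peptide. Per the authors' deposited table H2bc18 rose by 1.21 ± 0.16, H3c2 by 1.12 ± 0.20, H3c4 by 1.09 ± 0.18 and H1f1 by 1.05 ± 0.17. These are genes of the histones H2B, H3 and H1, and reads could be split among similar copies within a histone family. Of 38 histone genes tested 28 rose and 0 fell, among 126 risen of 9878 genes, a set defined after its genes were seen to lead the table. Other short RNAs that, like histone mRNAs, lack a poly(A) tail also had positive fold changes (8 of 8, median 0.48, 2 passed). The cell proliferation list, fixed beforehand, had positive fold changes for 21 of 21 genes, of which 4 rose in the test over all genes and 13 when adjusted over the list alone (list adjusted p = 5.07e-13, and 0.00281 with a correlation of 0.2). The mitotic genes Cdc20 (0.78 ± 0.19), Ccnb2 (0.74 ± 0.20) and Ccna2 (0.56 ± 0.17) and the proliferation marker Mki67 (0.52 ± 0.14) rose in the authors' deposited table. With the statistics divided by their spread none of these 4 passed (adjusted p = 0.0716, 0.144, 0.217 and 0.126), and Ccna2 did not pass with no filter on low counts (0.0729). Paneth cell markers, antimicrobial products of the crypt base, had positive fold changes in 10 of 11 genes, 5 risen and 8 adjusted over the list alone (adjusted p = 6.72e-11, and 9.01e-04 with a correlation of 0.2). Among them were Defa20 (0.94 ± 0.18, identical in value to Defa2), Defa24 (0.78 ± 0.15), the lectin Itln1 (0.74 ± 0.17) and Mmp7 (0.79 ± 0.20), which activates defensins, in the authors' deposited table.

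Transcript length moved with the peptide comparison in the ileum on CHD. Across 11680 genes, which are not independent replicates, Spearman's rho between the statistic and the length was -0.37, and length and GC content together accounted for 17.1% of the variance of the statistics. The median transcript length was 1255 nt for higher genes and 4447 nt for lower genes, against 3024 nt for all. Histone transcripts had a median length of 530 nt and a median fold change of 0.83, where genes of the same lengths had 0.23. Paneth markers had 709 nt and 0.50, against 0.16, and proliferation genes 3031 nt and 0.48, against 0.04. Corrected for length and GC content, 112 genes passed, 51 higher and 61 lower, in place of 213, 126 higher and 87 lower, of 9878 genes in the authors' deposited table, and 93 genes passed in both. Of the genes named for this comparison Agr2, B2m, Ccna2, Ccnb2, Hsp90b1, Mmp7, Per3 and Psmb8 no longer passed after the correction. The proliferation, Paneth and antimicrobial lists still did (adjusted p = 3.21e-15, 6.69e-06 and 1.22e-04). Divided by their spread of 1.17, the statistics passed for 59 genes, 39 higher and 20 lower, and B2m, Cd36, Fos, Hsp90b1, Klf4, Klf6, Mmp7, Per3 and Psmb8 were also lost.

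**Figure D2:**
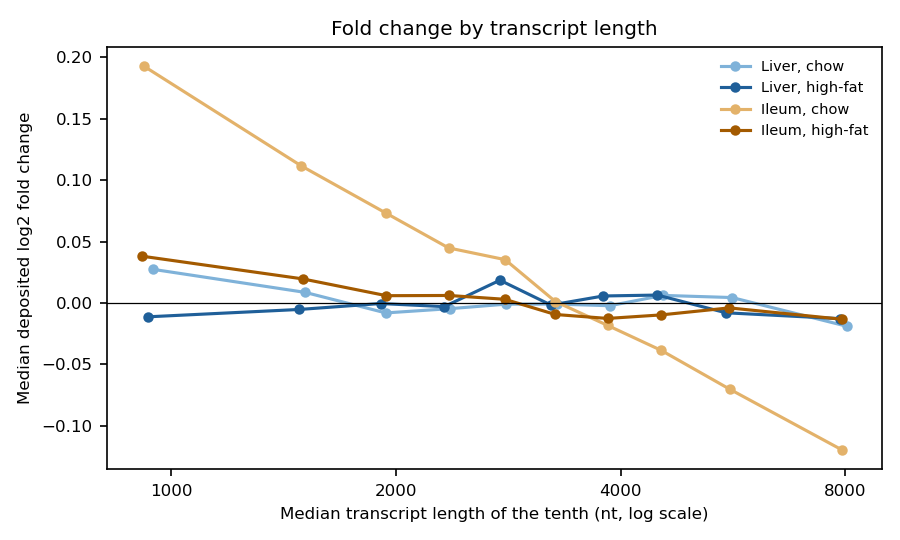
Median log2 fold change (vertical axis, from the authors' deposited tables, read as peptide over control) of genes in 10 equal groups by transcript length, against the median length of each group (horizontal axis, nt, log scale), 1 line per table. In the ileum on CHD the median runs from 0.19 in the shortest group to -0.12 in the longest, and the liver lines stay within 0.03 of 0.

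Other genes and lists of the ileum on CHD were also higher. The skeletal muscle gene Acta1 rose by 1.37 ± 0.23 in the authors' deposited table (adjusted p = 5.59e-06). This was the largest fold change that passed, while Ckm, the other measured skeletal muscle gene, stood at -0.13. Lypd8, a protein secreted by enterocytes that binds flagellated bacteria, rose by 1.01 ± 0.15 in the authors' deposited table (adjusted p = 3.63e-07). The epithelial antimicrobial defence list was higher (14 of 15 positive, 2 risen, 6 adjusted over the list alone, adjusted p = 2.16e-07, and 0.0238 with a correlation of 0.2). It shares Itln1, Lyz1 and Ang4 with the Paneth list, so these lists are not separate results. The antibacterial lectins Reg3b (0.41 ± 0.20, adjusted p = 0.364) and Reg3g (0.28 ± 0.19, adjusted p = 0.614) did not pass in the authors' deposited table. Goblet cell markers (10 of 10 positive, 1 risen, 2 adjusted over the list alone; adjusted p = 0.00358, but 0.161 with a correlation of 0.2) included the disulfide isomerase Agr2 (0.72 ± 0.16 in the authors' deposited table). Genes of the unfolded protein response were higher (21 of 22 positive, 2 risen and 1 fallen; adjusted p = 4.76e-05, but 0.159 with a correlation of 0.2). Pdia6 stood at 0.67 ± 0.13 and Hsp90b1 at 0.48 ± 0.14 in the authors' deposited table. Antigen presentation genes (15 of 17 positive, 2 risen, adjusted p = 0.00406, but 0.236 with a correlation of 0.2) included B2m (0.54 ± 0.16) and Psmb8 (0.68 ± 0.20) in the authors' deposited table. B and plasma cell markers were higher as a list (11 of 11 positive, median 0.37, adjusted p = 5.11e-05, but 0.0657 with a correlation of 0.2). Over all genes 0 of them passed, and 5 adjusted over the list alone. Of these 5, Blk, Cd79a, Cd19 and Mzb1 had no deposited adjusted p, so they were not tested over all genes. Their means were 12.2, 12.9, 15.1 and 18.4, near the cut of 10. Enterocyte markers were lower (9 of 11 negative, median -0.11, adjusted p = 0.0286, but 0.293 with a correlation of 0.2). Markers of T and NK cells (10 of 10 positive, adjusted p = 0.0345), enteroendocrine cells (8 of 10 positive, adjusted p = 0.0345) and fibroblasts (9 of 11 negative, adjusted p = 0.0345) and the interferon response list (19 of 29 positive, adjusted p = 0.0393) passed. With a correlation of 0.2 their adjusted p-values were 0.293, 0.293, 0.293 and 0.543. Corrected for length and GC content they were 0.223, 0.624, 0.295 and 0.122. Stem cell markers did not pass (median 0.06 with a mean statistic of -0.09, adjusted p = 0.820).

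In the ileum on CHD immediate early genes were lower as a list (11 of 15 negative, 3 fallen, 4 adjusted over the list alone; adjusted p = 5.11e-05, but 0.107 with a correlation of 0.2). Fos (-0.85 ± 0.20), Klf4 (-0.54 ± 0.13) and Klf6 (-0.53 ± 0.14) fell in the authors' deposited table. Socs3 fell by 1.02 ± 0.19, Ly6m by 1.12 ± 0.20, and the phosphatase Dusp6 by 0.86 ± 0.18 in the authors' deposited table. Abcc2, an apical export pump for conjugates, fell by 0.83 ± 0.17, the mitochondrial iron importer Slc25a37 by 0.80 ± 0.15 and the scramblase Ano6 by 0.79 ± 0.17 in the authors' deposited table. Clock genes were lower as a list (14 of 16 negative, 1 fallen, 4 adjusted over the list alone; adjusted p = 0.00358, but 0.235 with a correlation of 0.2). Per3 fell by 0.84 ± 0.24 in the authors' deposited table. Lipid absorption genes were lower (13 of 16 negative, adjusted p = 0.0185, but 0.293 with a correlation of 0.2), with 1 fallen, the fatty acid receptor Cd36 (-0.66 ± 0.20 in the authors' deposited table). Cholesterol synthesis genes were higher (20 of 23 positive, 0 passed over all genes or adjusted over the list alone; adjusted p = 4.76e-05, but 0.159 with a correlation of 0.2). Apolipoprotein genes (8 of 9 negative, adjusted p = 0.0185, but 0.235 with a correlation of 0.2) and adipocyte markers (9 of 10 negative, adjusted p = 0.00714, but 0.198 with a correlation of 0.2) were lower as lists. Markers of hepatocytes measured in the ileum were higher (5 of 5 positive, adjusted p = 0.0255, but 0.197 with a correlation of 0.2). Of 35 lists tested 19 passed, and 3 of them also with a correlation of 0.2. These were the antimicrobial defence, proliferation and Paneth lists, of which the first and last share genes. The bile acid genes Fgf15 (0.28 ± 0.21, adjusted p = 0.657), Fabp6 (0.04 ± 0.24, adjusted p = 0.975) and Slc10a2 (0.24 ± 0.21, adjusted p = 0.719) did not pass in the authors' deposited table.

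In the ileum on HFD, smooth muscle genes were lower with the peptide. Interferon response genes were higher as a list, but not with a correlation of 0.2 (adjusted p = 0.101). All 10 smooth muscle markers had negative fold changes, 5 fell in the test over all genes and 6 when adjusted over the list alone (list adjusted p = 1.35e-13, and 3.15e-05 with a correlation of 0.2). The contractile genes Actg2 (-0.75 ± 0.14), Myl9 (-0.57 ± 0.13), Acta2 (-0.55 ± 0.12), Cnn1 (-0.52 ± 0.14) and Des (-0.47 ± 0.13) fell in the authors' deposited table. Of 30 interferon response genes 26 had positive fold changes, 3 rose in the test over all genes and 5 when adjusted over the list alone (adjusted p = 5.83e-09). These were Ifit1 (0.90 ± 0.20), Oas1a (0.75 ± 0.20) and Rsad2 (0.70 ± 0.20), and the related Ifit1bl2 (0.81 ± 0.17) and Ifit1bl1 (0.80 ± 0.20) rose as well in the authors' deposited table. Fatty acid synthesis genes were lower (14 of 20 negative, 2 fallen, 6 adjusted over the list alone; adjusted p = 2.23e-06, but 0.101 with a correlation of 0.2). Thrsp, a regulator of lipogenesis, stood at -1.01 ± 0.17 and Me1 at -0.93 ± 0.19 in the authors' deposited table. Lipid absorption genes were lower as a list (12 of 15 negative, 0 passed over all genes, 5 adjusted over the list alone; adjusted p = 8.45e-05, but 0.105 with a correlation of 0.2). Among these Npc1l1, the intestinal cholesterol transporter, stood at -0.42 ± 0.14 (adjusted p = 0.140) in the authors' deposited table.

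Single genes of the ileum on HFD moved in both directions. Reg3a, an antibacterial lectin, rose by 0.96 ± 0.19, Tm4sf20 by 0.93 ± 0.16, Fbxo32 by 0.81 ± 0.15, Naip1, a sensor of bacterial proteins, by 0.79 ± 0.17, and Clec2d by 0.78 ± 0.14 in the authors' deposited table. Lypd8 rose by 0.70 ± 0.16, the bile acid receptor Nr1h4 by 0.65 ± 0.17 and the claudin Cldn2 by 0.62 ± 0.17 in the authors' deposited table. Entpd7 fell by 1.11 ± 0.16, Aldh4a1 by 0.94 ± 0.17, the angiotensin-converting enzyme gene Ace by 0.93 ± 0.17, Fbln1 by 0.90 ± 0.17, and Egln3 by 0.83 ± 0.16 in the authors' deposited table. Ang4, a Paneth cell antimicrobial protein, fell by 0.70 ± 0.16 in the authors' deposited table. Clock genes were lower (14 of 19 negative, 1 fallen, adjusted p = 0.00141, but 0.322 with a correlation of 0.2), with Per2 at -0.91 ± 0.18 in the authors' deposited table. Apolipoprotein genes (9 of 10 negative, adjusted p = 0.00134, but 0.123 with a correlation of 0.2) and adipocyte markers (9 of 10 negative, adjusted p = 3.83e-04, but 0.101 with a correlation of 0.2) were lower. Cholesterol synthesis genes were higher (19 of 23 positive, 0 passed over all genes or adjusted over the list alone; adjusted p = 0.00292, but 0.448 with a correlation of 0.2). Of 34 lists tested 8 passed, and the smooth muscle list alone passed with a correlation of 0.2. Cell proliferation (14 of 21 negative, adjusted p = 0.801) and Paneth markers (7 of 11 negative, adjusted p = 0.103) did not pass as lists, nor did the unfolded protein response (15 of 22 negative, adjusted p = 0.0526). Fgf15 (0.00 ± 0.15, adjusted p = 0.999), Fabp6 (0.34 ± 0.21, adjusted p = 0.680), Slc10a2 (0.20 ± 0.17, adjusted p = 0.843), Reg3b (0.35 ± 0.18, adjusted p = 0.546) and Reg3g (0.40 ± 0.18, adjusted p = 0.435) did not pass in the authors' deposited table. In all 96 of 7622 genes passed in the authors' deposited table, 31 higher and 65 lower. GC content moved with this comparison: Spearman's rho between the statistic and GC content across 12054 genes was -0.31, and the median GC content was 46.7% for higher and 54.0% for lower genes. Corrected for length and GC content, 70 genes passed and the smooth muscle, interferon and fatty acid synthesis lists still did (adjusted p = 1.74e-13, 4.07e-08 and 3.02e-05), while Des and Rsad2 no longer passed as genes. The Paneth and unfolded protein response lists then passed as lower (adjusted p = 0.0145 and 0.0311).

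**Figure D3:**
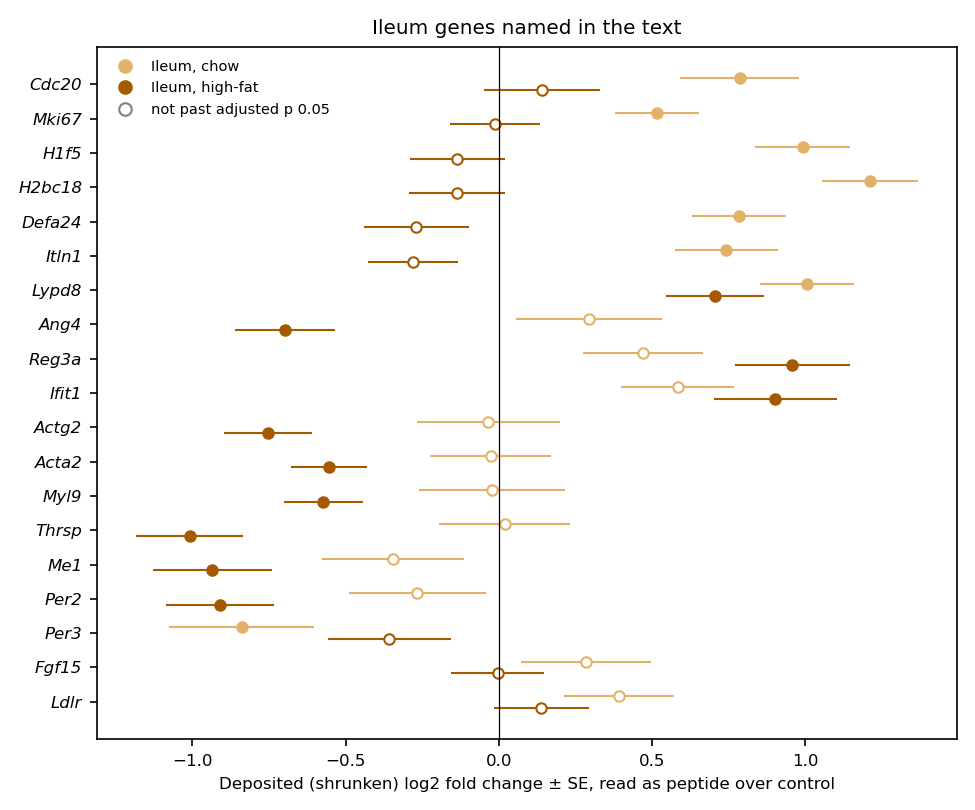
Log2 fold changes of 19 ileum genes named in the text, from the authors' deposited tables, read as peptide over control (horizontal axis, log2 units), on CHD (light) and HFD (dark). Bars are the authors' SE and open points did not pass an adjusted p of 0.05: Lypd8 lies right of 0 with filled points on both diets, H2bc18 lies at 1.21 on CHD and -0.14 on HFD, and Actg2 at -0.75 on HFD.

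Between the diets, the peptide effect in the ileum differed in 38 of 11658 genes, 9 more positive and 29 more negative on HFD. The difference, HFD minus CHD, was -1.39 ± 0.23 (SE) for H1f1, -1.35 ± 0.22 for H2bc18, -1.27 ± 0.24 for H2ac20, -1.05 ± 0.23 for Defa24 and -1.02 ± 0.22 for Itln1. Short RNAs that, like histone mRNAs, lack a poly(A) tail had a median fold change of 0.48 on CHD (8 of 8 positive, 2 passed) and -0.31 on HFD (0 of 9 positive, 2 passed), a set chosen after its values were seen. The difference was 1.15 ± 0.25 for Fbxo32, 1.09 ± 0.27 for the stress-induced transcription factor Atf3, 1.04 ± 0.23 for Lhfpl2, 1.03 ± 0.21 for the laminin gene Lama3 and 0.98 ± 0.23 for the transporter Slc17a4. Paneth markers (10 of 11 more negative, median difference -0.69, adjusted p = 1.83e-12) and cell proliferation genes (21 of 21, -0.53, adjusted p = 6.34e-12) were more negative on HFD as lists. Over all genes 2 Paneth markers passed, and 7 adjusted over the list alone, while 0 proliferation genes passed either way. With a correlation of 0.2 the adjusted p-values of the Paneth and proliferation lists were 1.74e-04 and 0.00620. Unfolded protein response genes (20 of 22 more negative, median -0.36, adjusted p = 2.37e-07) and B and plasma cell markers (9 of 11, -0.55, adjusted p = 3.42e-05) were also more negative as lists. Over all genes 1 unfolded protein response gene passed as more negative (Chac1) and 1 as more positive (Atf3). Of the B and plasma cell markers, some with means near the cut of 10, 0 passed over all genes and 5 adjusted over the list alone. With a correlation of 0.2 both lists had an adjusted p of 0.0578. Corrected for length and GC content, 15 genes differed, 5 more positive and 10 more negative, all among the 38, and Defa24 no longer passed. The fatty acid oxidation and interferon lists then passed as more positive on HFD (adjusted p = 0.0472 for each, against 0.0568 and 0.0643 without the correction). Per the authors' deposited tables, and among 7619 genes tested in both, Lypd8, Clec2d and 1810065E05Rik rose on both diets (3 genes, expected 0.431, one-sided Fisher's exact test, p = 0.00887). A further 7 fell on both in the authors' deposited tables (Ano6, B4galt5, Crybg2, Eepd1, Entpd7, Fbln1 and Npl, expected 0.706, p = 5.75e-06 by the same exact test). As in the liver, the exact tests take genes as independent.

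**Figure D4:**
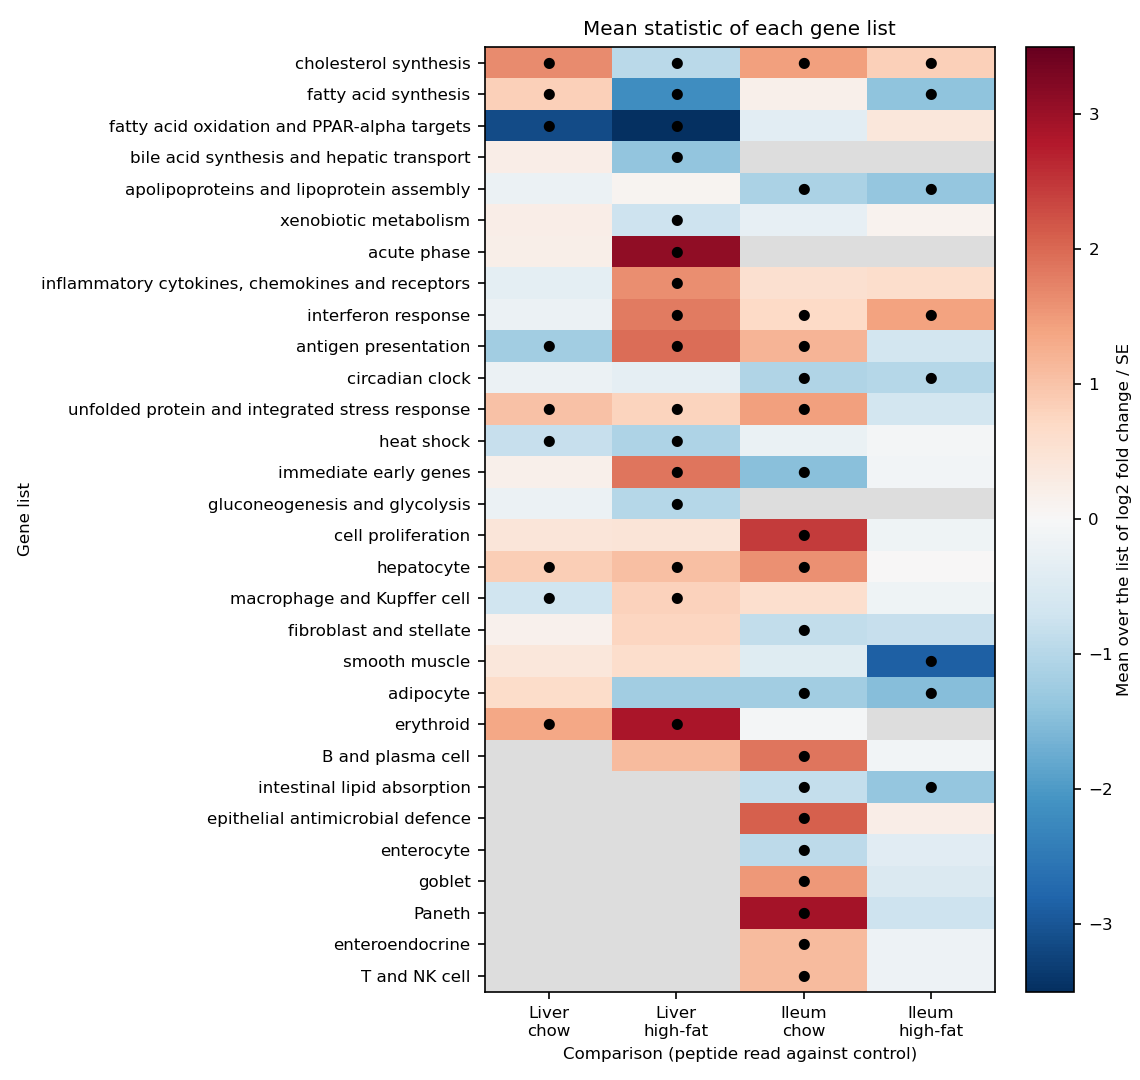
Mean over each list of the statistic (log2 fold change over SE, colour scale, computed from the authors' deposited tables) for the 30 gene lists that passed in at least 1 of the 4 comparisons (columns). Dots mark an adjusted p under 0.05 with a correlation of 0.01 and grey marks lists not tested there: fatty acid oxidation is the darkest blue field, in both liver columns, and smooth muscle in the ileum on HFD comes next.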

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

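The tests of hepatocyte share and of lymphoid follicles, and the corrections for GC content and transcript length as a setting, were chosen after the results were seen. The gene and list values in the 2 paragraphs on liver and ileum are differences of log2 fold changes, HFD minus CHD, that passed the test of the difference itself.

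In the liver 15 genes had a peptide effect that differed between the diets. More positive on HFD were Mt2 (2.40), Mt1 (1.54), Junb (1.04), Csad (1.00) and Klf9 (0.81). More negative were Tsku (-1.46), Tfrc (-1.45), Ppp1r3b (-1.08), Fasn (-1.06), Hmgcr (-1.02), Cyp7a1 (-0.96) and Srebf1 (-0.87). Cyp7a1 did not pass after the correction for GC content and transcript length (adjusted p = 0.0720), nor Fasn, Junb and Ppp1r3b with the shrinkage undone (0.0539, 0.0993 and 0.0539). Among lists, the median difference was 0.53 for antigen presentation, 0.44 for inflammatory cytokines and receptors, 0.38 for the interferon response, 0.38 for immediate early genes, 0.36 for the acute phase and 0.27 for macrophage markers. It was -0.46 for fatty acid synthesis, -0.37 for cholesterol synthesis, -0.15 for xenobiotic metabolism and -0.12 for bile acid synthesis and transport. The macrophage, xenobiotic and bile acid lists did not pass with a correlation of 0.2 (adjusted p = 0.0765, 0.374 and 0.183).

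In the ileum 38 genes differed. More positive on HFD were Fbxo32 (1.15), Atf3 (1.09), Lhfpl2 (1.04), Lama3 (1.03) and Slc17a4 (0.98). More negative were H1f1 (-1.39), H2bc18 (-1.35), H2ac20 (-1.27), H4c14 (-1.24), Acta1 (-1.18), Chac1 (-1.17), H3c1 (-1.16), Defa24 (-1.05) and Itln1 (-1.02). Acta1 itself was positive on both diets, with log2 fold changes of 1.37 on CHD and 0.19 on HFD. Corrected for GC content and transcript length, Acta1, Chac1, H3c1 and Defa24 no longer passed (adjusted p = 0.108, 0.192, 0.159 and 0.0990), and Chac1 did not pass with no filter on low counts (0.0688). The median difference was -0.69 for Paneth markers, -0.55 for B and plasma cell markers, -0.53 for cell proliferation, -0.43 for smooth muscle markers, -0.36 for the unfolded protein response, -0.31 for antigen presentation, -0.28 for epithelial antimicrobial defence, -0.28 for fatty acid synthesis, -0.26 for goblet cell markers, -0.25 for T and NK cell markers and -0.20 for enteroendocrine markers, and 0.15 for immediate early genes. Of these lists the Paneth and proliferation lists passed with a correlation of 0.2, though 0 single proliferation genes passed. The antimicrobial defence list shares Itln1, Lyz1 and Ang4 with the Paneth list. The T and NK cell and enteroendocrine lists did not pass with a correlation of 0.05 (adjusted p = 0.0868 and 0.0552), nor after the correction (0.108 and 0.262).

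Lower fatty acid oxidation genes in the liver were seen on both diets. Corrected for GC content and transcript length, the mean score of the list stayed at -3.12 or beyond in both tables, which argues against these as the whole cause. A lower share of hepatocytes would lower hepatocyte markers as well, and their medians were 0.0796 on CHD and 0.14 on HFD. On HFD this is a weaker check, because the marker list shares Fgb and Hpx with the acute phase list, which was higher. A difference in the time of day of collection may contribute and stays open: 1 clock gene passed adjusted over the list alone on CHD and 5 on HFD. The same limit holds for other genes that changed on HFD and for the differences between diets in liver. For those differences 0 clock genes passed adjusted over the list alone. An effect of the peptide, which the design names, is among the open explanations.

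Higher proliferation genes in the ileum on CHD had a mean score of 2.31 after the correction for GC content and transcript length, which argues against these as the whole cause. More crypt and less villus in the pieces could raise them and stays open, since stem cell markers had a median of 0.0578 with an SD of 0.29 over 7 genes. Enterocyte markers had a median of -0.11 with an SD of 0.18 over 11 genes and Paneth markers, of the crypt base, a median of 0.50, which both go with more crypt. More lymphoid follicle could as well, since B cell markers, some with means near the cut of 10, had a median of 0.37, under the 0.48 of the proliferation list. A difference in the time of day of collection also stays open for the ileum. The clock list was lower on CHD and HFD (limma's list test, adjusted p = 0.00358 and 0.00141, but 0.235 and 0.322 with a correlation of 0.2). On each diet 4 clock genes passed adjusted over the list alone, 1 of those on HFD as higher. For the differences between diets in ileum 0 did. An effect of the peptide on dividing cells cannot be told apart from these explanations.

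Lower smooth muscle genes in the ileum on HFD had a mean score of -2.67 after the correction, which argues against GC content and transcript length as the whole cause. Less muscle layer in the pieces may account for them and stays open: markers of enteric neurons and glia, which lie in that layer, had a median of -0.0878 with an SD of 0.13 over 4 genes. Of the 2 measured skeletal muscle genes, Ckm fell by 0.88 ± 0.19 (SE) in the authors' deposited table (adjusted p = 0.00187), and the other, Acta1, stood at 0.19. An effect of the peptide on smooth muscle cannot be told apart from less muscle layer or from a difference in the time of day of collection.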

How the results depend on the processing

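The threshold of 0.1 and the removal of the filter on low counts were planned, and all other alternatives were chosen after the data were seen. At a threshold of 0.1, 48 genes passed in liver on CHD, 217 in liver on HFD, 340 in ileum on CHD and 147 in ileum on HFD, in place of 28, 129, 213 and 96, because the threshold was wider. With scores divided by their own spread, 71 (38 higher, 33 lower), 80 and 59 passed in the first 3 of these. Corrected for GC content and transcript length, 112 passed in ileum on CHD (51 higher, 61 lower) and the ileum effect differed between diets in 15 genes in place of 38, and the cause was not tested. With the shrinkage undone the liver effect differed in 9 genes in place of 15, and the cause was not tested. Counted as transcripts, 194 passed in liver on HFD, since genes have several. The other total counts stayed within 1.5 times the reported ones, but not all counts by direction did. With no filter on low counts, 5 genes in place of 9 were more positive on HFD in the ileum. With a mean of at least 50, 4 in place of 7 were more positive on HFD in the liver.

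No list that passed reversed. The alternatives leave a named gene's deposited fold change as it is and alter its p-value alone, so its direction was not put to a test. With no filter on low counts 24 named genes no longer passed and 2 newly passed, with scores divided by their spread 27 and 13, and with the GC and length correction 22 and 2. Among genes named in the text, Pklr, Sc5d and Neat1 in liver on CHD no longer passed with no filter (adjusted p = 0.0664, 0.0771 and 0.134), nor Cxcl10 in liver on HFD (0.0503). In ileum on CHD B2m, Ccna2, Cd36, Hsp90b1 and Psmb8 were lost with no filter (0.0551, 0.0729, 0.0721, 0.0677 and 0.0606), on HFD Cldn2, Cnn1, Des and Rsad2 (0.0573, 0.0646, 0.0540 and 0.0785), and for the diet dependence Chac1 (0.0688). Neat1 was also lost with a mean of at least 10 or 50 and Rsad2 with at least 10 (0.0839, 0.0516 and 0.0532). With scores divided by their spread Cry1, Gpam and Cxcl10 in liver on HFD had an adjusted p of 0.0564, 0.0805 and 0.0810. In ileum on CHD Cdc20, Ccnb2, Ccna2 and Mki67 had 0.0716, 0.144, 0.217 and 0.126, Fos, Klf4 and Klf6 0.0524, 0.0503 and 0.126, and Mmp7, B2m, Psmb8, Hsp90b1, Per3 and Cd36 0.0779, 0.187, 0.195, 0.206, 0.159 and 0.216. Of the lists, 15 calls ended with a correlation of 0.05, 51 with 0.2, 8 with ranks, 6 with the correction and 5 with genes that had a deposited adjusted p alone. The last 5 were antigen presentation and macrophage markers in liver on CHD, the unfolded protein response in liver on HFD, and hepatocyte and T and NK cell markers in ileum on CHD. That setting could not alter the lists of the diet differences, where every gene had a computed adjusted p. After the correction, 5 lists newly passed: xenobiotic metabolism in ileum on CHD (adjusted p = 0.0111), and in ileum on HFD and for the ileum diet dependence those given with these comparisons.

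No paired analysis was possible because the deposited tables hold no values of single libraries. For this reason leaving out each replicate, other size factors or upper-quartile factors, refits with other count models, the stricter count filter, the pseudocount, the fit of all 12 samples of a tissue, the list tests with an estimated correlation or with fry and other splits of the samples were not run. What depth limits is unknown.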

Other observations

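The set of short RNAs without a poly(A) tail and the set of histone genes were both chosen, and tested, after the results were seen.

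Short RNAs without a poly(A) tail, such as the RNA parts of the ribonucleases MRP and P (Rmrp, Rpph1), telomerase RNA (Terc) and small Cajal body RNAs, were measured with no list test. Their median log2 fold change in the ileum was 0.48 on CHD, with 8 of 8 positive and 2 passed, and -0.31 on HFD, with 0 of 9 positive and 2 passed. On CHD Scarna6 (0.81 ± 0.22 SE) and Scarna10 (0.76 ± 0.21) rose in the authors' deposited table, while Rmrp, Rpph1 and Terc did not pass (adjusted p = 0.611, 0.0808 and 0.0757 in the authors' deposited table). On HFD Rmrp fell by 0.68 ± 0.13 (SE) and Rpph1 by 0.58 ± 0.14 in the authors' deposited table (adjusted p = 2.27e-04 and 0.00792). In liver the medians were 0.05 on CHD and -0.21 on HFD.

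Replication-dependent histone mRNAs also lack a poly(A) tail. Their median was 0.83 in the ileum on CHD and -0.06 on HFD, and 0.33 and 0.21 in liver. In the ileum on CHD their score exceeded that of genes of the same transcript length by 2.93 ± 0.24 (SE) on average. The set was chosen because its genes led this comparison, and similar copies can share reads. This excess therefore cannot decide whether length is the whole cause. A higher recovery of short RNAs in the peptide libraries is a candidate explanation for part of the histone change. The other short RNAs without a tail had a median of 0.480 there. The libraries held ribosomal RNA-depleted total RNA, so a missing tail alone need not alter recovery. On HFD the other RNAs did not move with the histone genes. In the ileum on HFD their median was -0.31 (0 of 9 positive) against -0.06 for the histone genes. In liver on HFD the histone median was positive while that of the other RNAs was negative. A larger share of dividing cells, with 21 of 21 proliferation genes positive, is another explanation, and these are not exclusive.

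Xist had mean normalized counts of 1876 in liver on CHD, 3415 in liver on HFD, 3126 in ileum on CHD and 4623 in ileum on HFD in the authors' deposited tables. Ddx3y, Eif2s3y, Kdm5d and Uty, on the Y chromosome, were listed at 0 in each of the authors' deposited tables.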
